A study of Mus musculus with 15 samples.

How the data were processed

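Signals of 34760 probe sets on a gene-level array were used for 15 samples of isolated left ventricular cardiomyocytes. Per the labels, hearts were digested with collagenase, calcium was restored stepwise, and over 90% of the cells were calcium-tolerant cardiomyocytes that a few inflammatory or endothelial cells could accompany. The deposited values were log2 signals that the authors had normalized, with a range of 0.234 to 13.01 and 0 missing. The submitters' processing notes name MAS5, and its version and its part in the normalization are not given in the sources used here. The plan made before the data were examined allowed for linear or log2 values, and the values were log2, so they were used as they stood. The proton-exposed part of the study was not analysed here.

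Of the probe sets, 21640 had 1 gene symbol, 1321 had several and 11799 had none. Probe sets with 1 symbol, of which 21553 had their gene in the gene table, gave 19937 named genes, each represented by 1 probe set. The 9969 genes with the highest mean signal (above 5.5125 on the log2 scale, the 50th percentile) were tested. The filter on mean signal limited the tests to these genes, and the number of arrays (1 to 3 per group) set the precision.

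Genes were tested with limma 3.58.1 in R 4.3.3 by a linear model with 6 group means (sham and 5 iron days) and moderated variances with an intensity trend, with 9 residual degrees of freedom. Comparisons were each iron day minus sham, all iron days minus sham, late iron (days 7, 14 and 28) minus early iron (days 1 and 3), and an F test among the iron days. A model with sham days 1 and 3 apart gave their difference. P values were adjusted by Benjamini and Hochberg's method over all genes tested, with a threshold of 0.05, and within each list where stated. The pipeline was tested on simulated data with 9969 genes, where it recovered 93 of 100 differences of 1 log2 unit and 54 of 100 of 0.5 on day 3 (91 and 46 on day 28), and called 4 and 8 unchanged genes. The simulated errors were normal and independent between genes and arrays, so genes that vary together were not covered.

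The genes named were, by a rule fixed before the data were examined, the 8 with the largest difference in each direction among those that passed and whose arrays did not overlap, or the 4 with the smallest p where fewer than 4 qualified, and the 12 with the smallest p in the F test. Members of lists and the genes said to be picked after the values were seen were named besides. The 35 lists (25 pathways, 10 cell types) held 788 symbols, of which 714 were on the array as single genes and 612 were tested. Lists with 4 or more tested members were compared with all other genes by limma's camera test with a preset correlation of 0.01, and again with an estimated correlation and with the fry test. Some genes belong to more than 1 list. Marker scores were means over a list's genes, each centred over the arrays. Small nucleolar RNAs, other short RNAs and histone genes were grouped by annotation, and thymocyte and lung genes were listed, after the values were seen.

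Alternatives tried were quantile normalization, median centring, no filter and a stricter filter (6646 genes), no intensity trend, array weights, all probe sets, a replicate block, only the arrays compared, the sham arrays of 1 day as control, and leaving out each array. Marker scores as covariates and leaving out 3 arrays together were added later. Replicate numbers were not used to pair samples. Correlations between residuals of arrays with the same number ran from -0.39 to 0.57 over 31 pairs (median 0.088), and 14 of these were above 0.1. For arrays with other numbers they ran from -0.57 to 0.49 over 50 pairs (median -0.065), and 13 were above 0.1. Whether the numbers pair the samples was thus not settled. Comparisons that share the sham arrays were set against 50 simulations of unchanged groups. Tables were also handled with pandas 2.3.3 and numpy 2.4.6 and figures drawn with matplotlib 3.10.9 in Python 3.11.15.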

Results

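RNA from isolated left ventricular cardiomyocytes, the contractile muscle cells of the main pumping chamber, was measured on 15 gene expression arrays with 34760 probe sets each. The cells came from male C57Bl/6NT mice aged 8 to 9 months that had received either a sham exposure or 0.15 Gy of iron ions over the whole body. The ions had an energy of 1 GeV per nucleon and a linear energy transfer near 151 keV per µm. Iron ions are heavy charged particles that also occur in galactic cosmic rays. Iron-exposed cells were collected on day 1 (3 arrays), day 3 (3 arrays) and days 7, 14 and 28 (2 arrays each), and sham cells on day 1 (2 arrays) and day 3 (1 array). The comparisons ask how the transcripts of these cells differed from sham at each day, and whether the difference was delayed, as the series title puts it. The sham arrays used here are from days 1 and 3, so time and exposure were not separated for days 7, 14 and 28. Nothing in the labels says that arrays of a group came from separate mice. The p-values therefore measure the spread between these arrays, which may be technical, and the small number of arrays limits the precision.

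Values are log2 differences of normalized signal with the standard error (SE) of the fit, for 9969 genes tested with limma. Adjusted p values are Benjamini-Hochberg adjusted over those genes. The genes named first in each direction had the largest differences among those that passed and whose arrays did not overlap between the sides. Groups of genes were 33 tested lists fixed before the data were examined, each compared with all other genes by limma's camera test. No list in any comparison passed that test when the correlation between its genes was estimated from the arrays in place of the preset 0.01, and that second adjusted p stands beside each call. The median difference over all genes tested lay between -0.0414 and 0.0366 in these comparisons. The first 3 principal components held 42.2%, 15.9% and 12% of the variance, and arrays correlated pairwise at r = 0.902 to 0.995 across genes.

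On day 1 the genes that passed were lower in the iron arrays, and those with the largest falls are genes of antigen presentation. No list of antigen presentation genes was tested. H2-Aa, which encodes a chain of a class II histocompatibility protein, fell by 1.61 on the log2 scale (SE 0.224, 3 iron and 3 sham arrays). Cd74, the chaperone of those proteins, fell by 1.61 (SE 0.244), H2-Ab1 by 1.45 (SE 0.230) and H2-Eb1 by 1.33 (SE 0.211). Igf2, a fetal growth factor, fell by 1.22 (SE 0.195), and the transcript F630028O10Rik by 0.99 (SE 0.146). Each of the 6 had an adjusted p of 0.0447. The genes closest to passing on the higher side were Amy1 (0.96, adjusted p = 0.255), Cntn5 (0.72, adjusted p = 0.255), Homer1 (0.32, adjusted p = 0.262) and Mtm1 (0.46, adjusted p = 0.276).

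Several lists of markers of other cells were called lower on day 1. The lymphocyte list, which holds the class II genes above, had a median of -1.27, with 4 of 8 members lower and 5 lower adjusted over the list alone (camera adjusted p = 2.50e-09; adjusted p = 0.293 with an estimated correlation). The median was -0.905 without the sham day 3 array, in which thymocyte and lung genes stood 2.35 and 1.03 above their medians over arrays, against values under 0 in both sham day 1 arrays. Among fibroblast markers, 14 of 15 were lower adjusted over the list alone and 14 at an unadjusted p under 0.05 in limma, but 0 adjusted over all genes. Their median was -0.82 (camera adjusted p = 1.66e-16; adjusted p = 0.293 with an estimated correlation), and it ranged from -1.13 to -0.515 over the alternatives run. Lum, a collagen-binding proteoglycan, stood at -1.16 (SE 0.255, adjusted p = 0.255). Macrophage and monocyte markers had a median of -0.87, with 15 of 17 lower adjusted over the list alone (camera adjusted p = 1.65e-15; adjusted p = 0.293 with an estimated correlation). Extracellular matrix genes (median -0.59, 12 of 23 lower adjusted over the list alone) and interferon response genes (median -0.34, 1 of 16) were called with camera adjusted p = 2.12e-14 and 3.02e-08, and each had an adjusted p = 0.293 with an estimated correlation. The same was found for the cell cycle list (median -0.083, camera adjusted p = 0.00434; adjusted p = 0.293 with an estimated correlation). Endothelial markers (median -0.50), angiogenesis factors (-0.19), the unfolded protein response (-0.19), inflammatory cytokines and NF-kB genes (-0.12) and atrial markers (-0.40) were called lower with camera adjusted p from 7.71e-05 to 0.0464, and all 5 had an adjusted p = 0.677 with an estimated correlation. Replicate 1 of iron day 1 stood apart, with an endothelial score of 0.52 beside -0.37 and -0.36 and an interferon score of 0.12 beside -0.19 and -0.51. Without it the medians were -0.88 for endothelial markers, -0.44 for angiogenesis factors and -0.90 for extracellular matrix, and without replicate 3 they were -0.26, -0.046 and -0.39. Angiogenesis factors stood at -0.052 without replicate 1 of sham day 1, and the unfolded protein response at -0.069 without the sham day 3 array. Atrial markers stood at 0.028 without replicate 1 of sham day 1.

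Lists of cardiomyocyte metabolism lay slightly above 0 on day 1. Fatty acid oxidation (median 0.10), the tricarboxylic acid cycle (0.093), the proteasome (0.13) and ion channels (0.15) were called higher with camera adjusted p from 0.00212 to 0.0173, and had an adjusted p = 0.677 with an estimated correlation. Oxidative phosphorylation followed with a median of 0.053 (camera adjusted p = 0.0332; adjusted p = 0.820 with an estimated correlation). The p53 targets, genes switched on by DNA damage, had a median of 0.089 (camera adjusted p = 0.0483; adjusted p = 0.429 with an estimated correlation), and their smallest p was that of Rrm2b, a ribonucleotide reductase subunit (0.38, SE 0.115, adjusted p = 0.288). Without the sham day 3 array the medians of ion channels and oxidative phosphorylation were 0.072 and 0.015. The total was 6 genes of 9969, against 1100 at an unadjusted p under 0.05 where 498 would be expected by chance. It was 363 without replicate 1 of iron day 1, and 1 without replicate 3 of iron day 3. It was 0 without any one of replicates 2 and 3 of iron day 1, replicates 1 and 2 of iron day 3, either array of iron days 14 and 28, replicate 1 of sham day 1 or the sham day 3 array (limma, 567 to 1134 genes at an unadjusted p under 0.05).

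**Figure D1:**
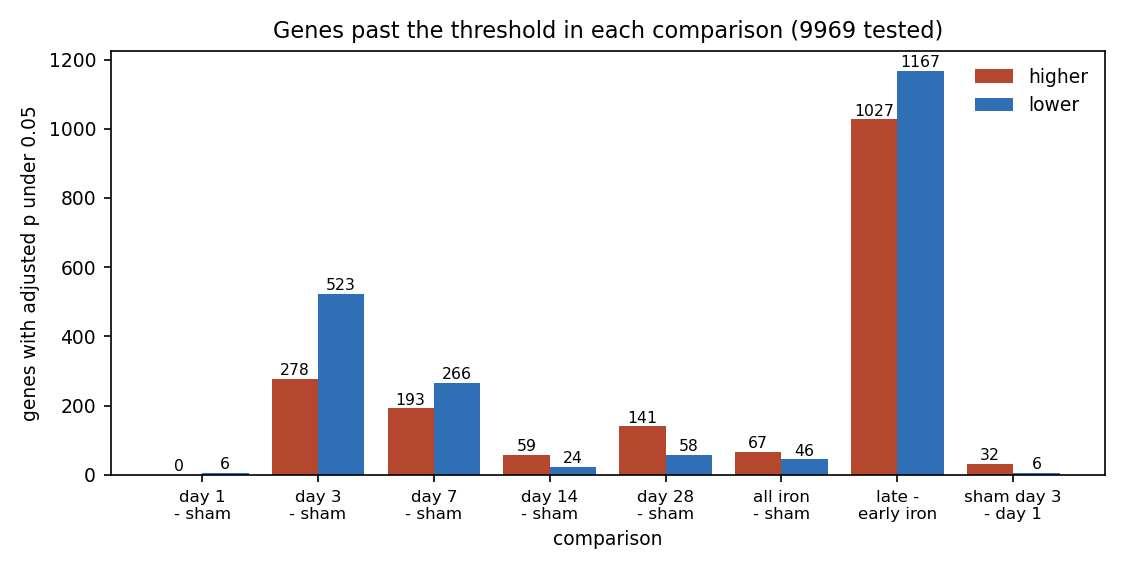
Number of genes with adjusted p under 0.05 in each comparison, of 9969 tested, with higher genes in red and lower genes in blue. Day 1 had 0 higher and 6 lower genes (367 and 733 at an unadjusted p under 0.05 in limma), day 3 had 278 and 523, and late minus early iron had 1027 and 1167.

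On day 3 several immediate early genes, which respond within minutes to stress and growth signals, were higher in the iron arrays. Atf3, a stress-induced transcription factor, rose by 1.77 (SE 0.439, adjusted p = 0.0289, 3 iron and 3 sham arrays) and the nuclear receptor Nr4a3 by 1.72 (SE 0.355, adjusted p = 0.0159). Gadd45g, a growth arrest gene, rose by 1.34 (SE 0.379, adjusted p = 0.0476), the deubiquitinase gene Otud1 by 1.83 (SE 0.459, adjusted p = 0.0305) and the inositol transporter gene Slc5a3 by 1.82 (SE 0.459, adjusted p = 0.0313). Short RNAs also rose, among them Mir133a-1, the gene of a muscle microRNA, by 1.78 (SE 0.355, adjusted p = 0.0132), and the small nucleolar RNAs Snord82 by 1.73 (SE 0.405, adjusted p = 0.0241) and Snord104 by 1.64 (SE 0.309, adjusted p = 0.0110). Of the 26 immediate early genes, 9 rose and 13 rose adjusted over the list alone, with a median of 0.61 (camera adjusted p = 4.93e-06; adjusted p = 0.539 with an estimated correlation). Dusp1, a phosphatase of stress kinases, was among them (0.99, SE 0.220, adjusted p = 0.0203).

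The strongest falls on day 3 were in genes of other cell types and of the extracellular matrix. Postn, a matrix protein of activated fibroblasts, fell by 2.0 (SE 0.275, adjusted p = 0.00536), Lum by 1.89 (SE 0.255, adjusted p = 0.00536) and Aspn by 1.88 (SE 0.266, adjusted p = 0.00625). The lipocalin gene Apod fell by 1.99 (SE 0.287, adjusted p = 0.00625), the complement regulator gene Cd55 by 1.88 (SE 0.368, adjusted p = 0.0121) and Tlr7, a sensor of viral RNA, by 1.86 (SE 0.317, adjusted p = 0.00745). Cd24a (-2.87, SE 0.822, adjusted p = 0.0486) and Car2 (-2.34, SE 0.570, adjusted p = 0.0274) had the greatest falls by this rule, and both are also abundant in red cell precursors. The mean score of the 2 erythroid markers was -1.07 (SD 0.983) on day 3 and 1.33 (SD 0.944) in sham. Of 15 fibroblast markers, 13 fell and 15 fell adjusted over the list alone, with a median of -1.18 (camera adjusted p = 3.11e-16; adjusted p = 0.412 with an estimated correlation). Of 17 macrophage and monocyte markers, 15 fell and 16 fell adjusted over the list alone, with a median of -1.38 (camera adjusted p = 3.44e-16; adjusted p = 0.412 with an estimated correlation). Extracellular matrix genes, 4 of which are also fibroblast markers, fell in 15 of 23 cases and in 18 adjusted over the list alone (median -0.87, camera adjusted p = 3.78e-15; adjusted p = 0.412 with an estimated correlation). Endothelial markers fell in 8 of 18 cases and in 13 adjusted over the list alone, with a median of -0.99 (camera adjusted p = 8.20e-07; adjusted p = 0.487 with an estimated correlation). Vwf, the von Willebrand factor gene, fell by 1.29 (SE 0.2, adjusted p = 0.00660).

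Smaller lists were lower with these markers on day 3, when the mean fibroblast score was -0.70 (0.61 in sham) and the mean macrophage score -0.85 (0.46 in sham). The lymphocyte list had 4 of 8 members lower (median -1.14, camera adjusted p = 0.000119; median -0.764 without the sham day 3 array) and the interferon response 2 of 16 (median -0.42, camera adjusted p = 1.66e-05). Smooth muscle and pericyte markers had 1 of 10 (median -0.61, camera adjusted p = 0.00212) and the cell cycle 3 of 15 (median -0.15, camera adjusted p = 0.0191). Adjusted over the list alone these counts were 4, 10, 6 and 4, and each list had an adjusted p = 0.412 with an estimated correlation. Angiogenesis factors had 6 of 22 members lower and 8 adjusted over the list alone (median -0.36, camera adjusted p = 0.00391; adjusted p = 0.641 with an estimated correlation). Among ribosomal proteins 3 of 30 fell and 4 fell adjusted over the list alone, where 1 also rose (median -0.19, camera adjusted p = 1.66e-05; adjusted p = 0.487 with an estimated correlation). The p53 targets had a median of 0.12 (camera adjusted p = 0.0395; adjusted p = 0.412 with an estimated correlation), with 2 of 17 higher and 5 adjusted over the list alone. These 2 were Gadd45a (0.59, SE 0.111, adjusted p = 0.0111) and Ddit4 (1.27, SE 0.268, adjusted p = 0.0168), which also respond to stresses other than DNA damage. The direct p53 targets Ccng1 and Mdm2, picked after the values were seen, stood at 0.018 (adjusted p = 0.852) and 0.032 (adjusted p = 0.875). Heat shock proteins had 1 of 18 members higher and 3 adjusted over the list alone (median 0.22, camera adjusted p = 0.0395; adjusted p = 0.779 with an estimated correlation). Ion channels had 3 of 20 higher and 1 lower, over the list alone too (median 0.22, camera adjusted p = 0.0138; adjusted p = 0.646 with an estimated correlation), and Kcnj2, an inward rectifier channel gene, rose by 0.56 (SE 0.140, adjusted p = 0.0292). Oxidative phosphorylation had a median of 0.079 (camera adjusted p = 0.00665; adjusted p = 0.803 with an estimated correlation), with 0 of 42 members passing in limma and 5 at an unadjusted p under 0.05. Without the sham day 3 array the medians of ion channels and oxidative phosphorylation were 0.12 and 0.042, and without replicate 1 of iron day 3 that of p53 targets was 0.057.

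In total 801 genes passed on day 3, 278 higher and 523 lower, and 229 of the lower but 22 of the higher differed by more than 2-fold. The count was 277, 126 and 375 without replicates 1, 2 and 3 of iron day 3, 174 without replicate 1 of sham day 1 and 269 without the sham day 3 array. The share of higher genes was 34.7%, and 46.1% with each array centred on its median. With the arrays' fibroblast and macrophage marker means as covariates, a setting chosen after the data were seen, 0 genes passed in limma and 576 had an unadjusted p under 0.05. The SE of the median gene was then 1.90 times as large. Genes of the 2 marker lists are part of these means, so their own move towards 0 was built in. The fibroblast mean also parted the sham arrays (0.615) from those of iron day 3 (-0.704), so this fit cannot tell the 2 apart. Matrix genes moved towards 0, as in Postn (-0.56, SE 0.35), and so did 3 of the 8 higher genes named above, Atf3 (0.55, SE 0.543), Gadd45g (0.43, SE 0.668) and Slc5a3 (0.37, SE 0.717). The other 5 kept most of their difference and lost precision: Snord82 (2.32, SE 0.854), Mir133a-1 (1.80, SE 0.528), Otud1 (1.74, SE 0.679), Nr4a3 (1.59, SE 0.567) and Snord104 (1.58, SE 0.666).

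**Figure D2:**
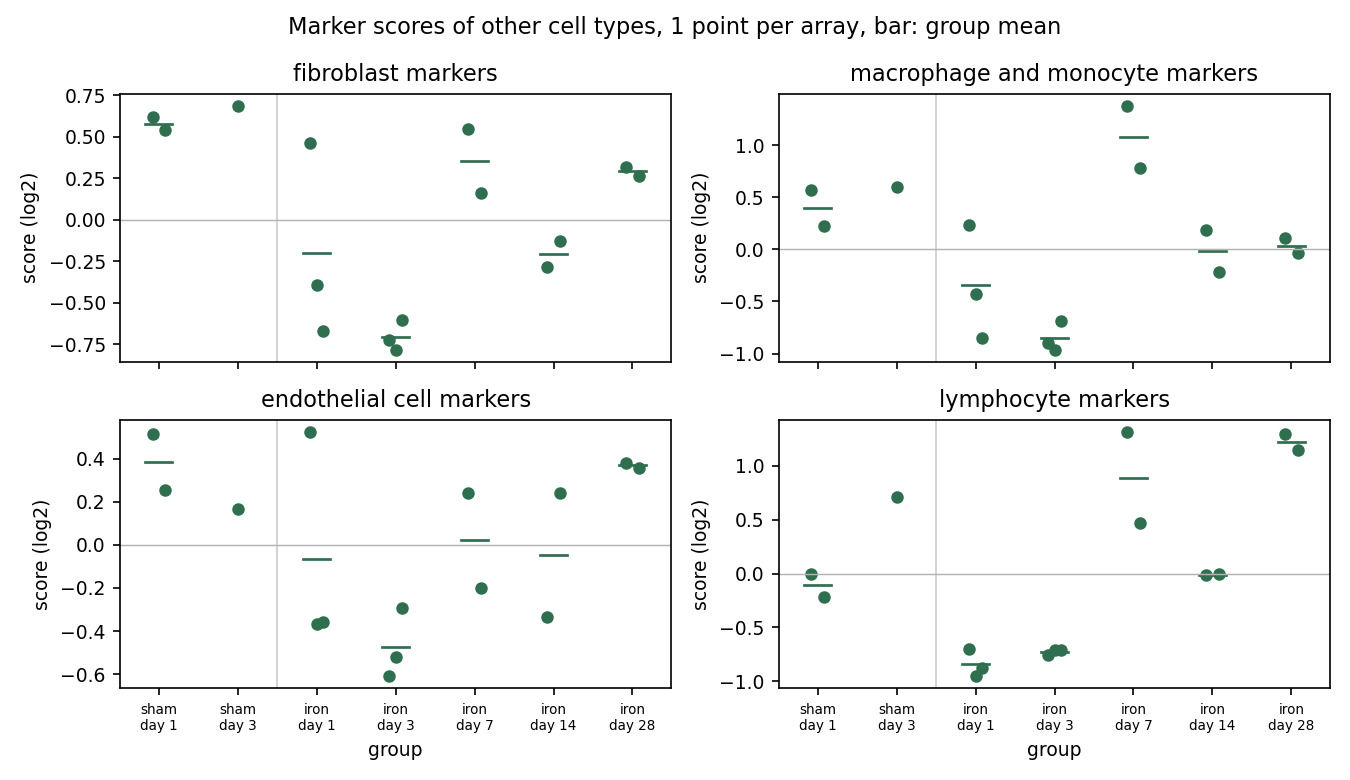
Mean log2 signal of the markers of 4 other cell types, each gene centred on its mean over 15 arrays, with 1 point per array and a bar at each group mean. Fibroblast scores lay between 0.54 and 0.69 in the 3 sham arrays and between -0.61 and -0.78 in the 3 iron day 3 arrays, while replicate 1 of iron day 1 stood at 0.46 beside -0.39 and -0.67 in the other 2.

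On day 7 the circadian clock genes were changed. Ciart, a repressor in the clock loop, fell by 2.67 (SE 0.255, adjusted p = 0.000228, 2 iron and 3 sham arrays), Per3 by 1.93 (SE 0.163, adjusted p = 9.39e-05) and Per2, another period gene, by 1.55 (SE 0.167, adjusted p = 0.000662). The clock output factors Dbp and Tef fell by 1.88 (SE 0.156, adjusted p = 9.39e-05) and 1.13 (SE 0.152, adjusted p = 0.00276). Arntl, the activator that peaks in opposite phase to Dbp, rose by 1.85 (SE 0.29, adjusted p = 0.00691) and Nfil3, which opposes Dbp at its targets, by 0.92 (SE 0.108, adjusted p = 0.00118). In the list of 18 clock genes 11 fell and 2 rose, with 12 and 2 adjusted over the list alone (median -0.61, camera adjusted p = 3.45e-07; adjusted p = 0.305 with an estimated correlation). The fibroblast marker median at this day was -0.20 and the macrophage marker median was 0.56. The other strong falls were in Aspn (-1.27, adjusted p = 0.0315), Prex2 (-1.21, adjusted p = 0.0278) and the matrix gene Hmcn1 (-1.05, adjusted p = 0.0149).

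The 8 largest rises on day 7 by this rule were in Snord73b and in 7 RNAs annotated as small nucleolar RNAs. Snord73b is a small nucleolar RNA by its name but is annotated in another class of short RNA. Small nucleolar RNAs guide chemical modification of ribosomal and spliceosomal RNA. Snord73b rose by 2.83 (SE 0.534, adjusted p = 0.0149), Snord82 by 2.79 (SE 0.453, adjusted p = 0.00773), Snora3 by 2.39 (SE 0.393, adjusted p = 0.00788) and Snord104 by 2.39 (SE 0.345, adjusted p = 0.00376). Snora74a, Snord33, Snora7a and Snord35b rose by 2.37, 2.31, 2.17 and 2.16. This class was looked at after the values were seen. By the gene annotation it held 27 tested small nucleolar RNAs, of which 0 passed on day 1 (limma; median -0.11), 13 rose on day 3 (median 0.63) and 21 on day 7 (median 1.35). On day 3 the score of replicate 1 was -0.56, beside 0.17 and 0.36 in the other 2 arrays and -0.78, -0.86 and -0.62 in sham. The 12 other short structured RNAs, which include Snord73b by its annotation, had 8 higher on day 7 (median 0.89).

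Lists of cardiomyocyte electrical and calcium genes were called lower on day 7, with a minority of their members passing. In the calcium handling list 5 of 19 fell and 8 fell adjusted over the list alone (median -0.23, camera adjusted p = 0.000304; adjusted p = 0.588 with an estimated correlation). Slc8a1, the sodium-calcium exchanger, fell by 0.73 (SE 0.109, adjusted p = 0.00575), the calcium store protein gene Casq2 by 0.26 (SE 0.0554, adjusted p = 0.0221) and Ryr2, the calcium release channel, by 0.33 (SE 0.0757, adjusted p = 0.0295). Of 20 ion channel genes 3 fell and 7 fell adjusted over the list alone (median -0.30, camera adjusted p = 0.00250; adjusted p = 0.588 with an estimated correlation). The potassium channel genes Kcnh2 (-0.73, SE 0.181, adjusted p = 0.0382) and Kcnq1 (-0.51, SE 0.136, adjusted p = 0.0489) led them. Sarcomere genes had 2 of 21 members lower and 7 adjusted over the list alone (median -0.075, camera adjusted p = 0.0366; adjusted p = 0.588 with an estimated correlation). Angiogenesis factors (median -0.29, 2 of 22 lower, also over the list alone, camera adjusted p = 0.0130) and smooth muscle and pericyte markers (median -0.53, camera adjusted p = 0.0450, 1 of 10 lower adjusted over the list alone) had an adjusted p = 0.588 with an estimated correlation. Without replicate 1 of iron day 7 the median was -0.11 for ion channels, -0.0091 for sarcomere genes and -0.46 for angiogenesis factors. Without replicate 2 it was -0.15 for sarcomere genes and -0.22 for smooth muscle and pericyte markers.

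Stress and immune lists were called higher on day 7, several of them mostly through replicate 1 of that day, again each with an adjusted p = 0.588 with an estimated correlation. Immediate early genes had a median of 0.65 (camera adjusted p = 1.43e-09), with 0 of 26 passing in limma, 20 at an unadjusted p under 0.05 and 16 higher adjusted over the list alone. Macrophage and monocyte markers had 1 of 17 members higher and 3 adjusted over the list alone (median 0.56, camera adjusted p = 7.13e-06). The lymphocyte list had 3 of 8 higher and 6 adjusted over the list alone (median 0.78, camera adjusted p = 0.000106), and inflammatory cytokines and NF-kB genes 2 of 16 and 4 (median 0.30, camera adjusted p = 0.000292). Glucocorticoid response genes had 3 of 16 and 6, with 1 lower (median 0.35, camera adjusted p = 0.000939). Heat shock proteins (median 0.33, camera adjusted p = 0.000304), the interferon response (0.20, camera adjusted p = 0.000904) and ribosomal proteins (0.14, camera adjusted p = 0.000304) had 1 member each higher, over all genes and adjusted over the list alone. Without replicate 1 of iron day 7 immediate early genes (0.13), inflammatory cytokines and NF-kB genes (0.032) and the interferon response (0.028) were not called, and the medians of macrophage markers and the lymphocyte list were 0.23 and 0.34. Lung and thymocyte genes also stood higher in that array (0.578 and 0.531 above their medians over arrays) than in replicate 2 (0.034 and 0.126). Without replicate 2 the medians were 1.20 for immediate early genes, 0.41 for the interferon response, 0.92 for macrophage markers, 1.27 for the lymphocyte list and 0.074 for ribosomal proteins. Hmox1, the heme-degrading enzyme, rose by 1.09 (SE 0.227, adjusted p = 0.0215) in an antioxidant list that was not called (median -0.019, camera adjusted p = 0.391). The day 7 total was 459 genes, 193 higher and 266 lower, and the higher share of 42.0% was 54.4% with each array centred on its median. It was 46 without replicate 1 of iron day 7, 265 without either array of iron day 28, and 138 and 159 without replicates 1 and 2 of sham day 1.

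**Figure D3:**
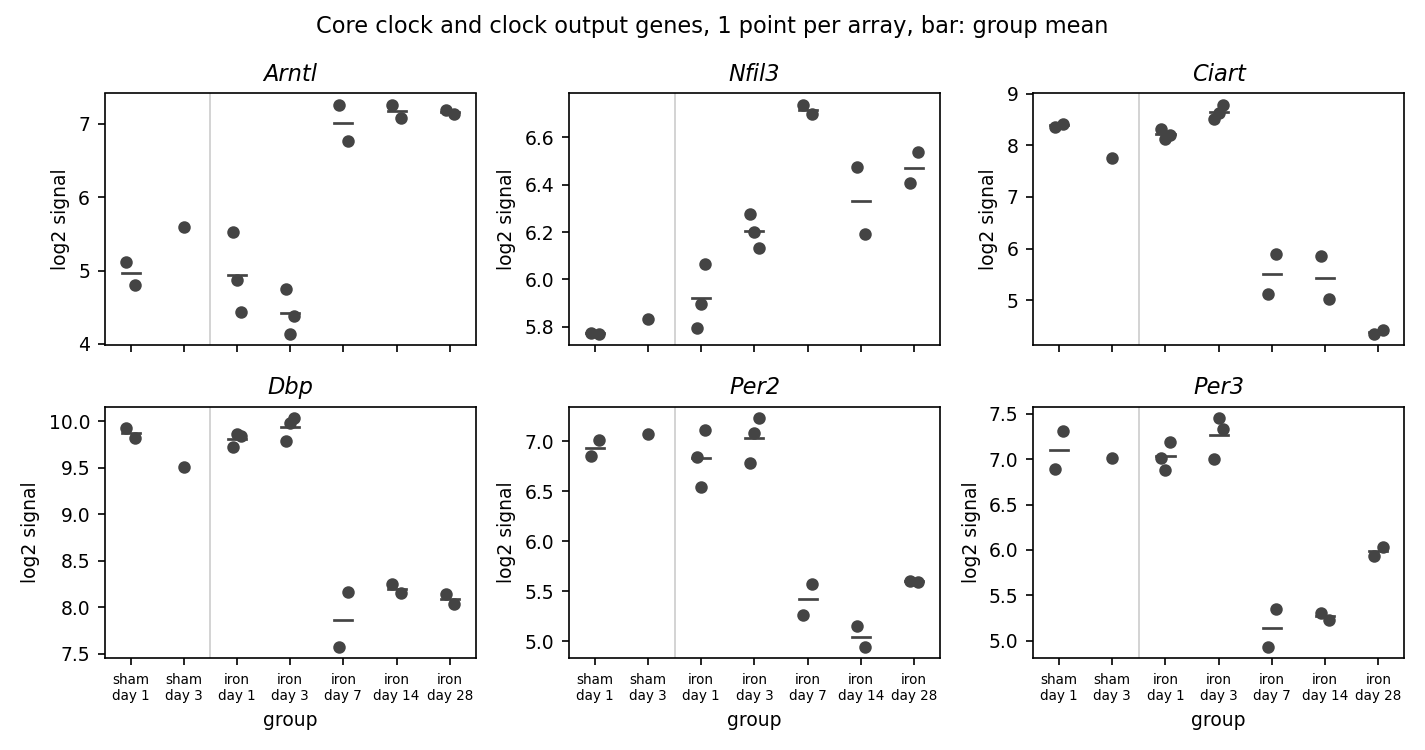
Log2 signal of 6 clock genes, with 1 point per array and a bar at each group mean. Arntl and Nfil3 were higher and Ciart, Dbp, Per2 and Per3 lower in the 6 arrays of iron days 7, 14 and 28 than in the sham arrays.

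On day 14 the same 2 kinds of transcript led the comparison. Ciart fell by 2.73 (SE 0.255, adjusted p = 0.000103, 2 iron and 3 sham arrays), Per2 by 1.93 (SE 0.167, adjusted p = 8.40e-05), Per3 by 1.80 (SE 0.163, adjusted p = 8.85e-05) and Dbp by 1.55 (SE 0.156, adjusted p = 0.000162). Arntl rose by 2.0 (SE 0.29, adjusted p = 0.00330). Clock genes fell in 8 of 18 cases and rose in 2, with 12 and 2 adjusted over the list alone (median -0.59, camera adjusted p = 6.35e-09; adjusted p = 0.176 with an estimated correlation). Snord73b rose by 3.62 (SE 0.534, adjusted p = 0.00377), Snord104 by 3.09 (SE 0.345, adjusted p = 0.000405) and Snora3 by 2.99 (SE 0.393, adjusted p = 0.00145). Snord82 (3.02), Snord33 (3.00), Snord47 (2.44), Snord35b (2.31) and Snord57 (2.26) rose too. Of the 27 small nucleolar RNAs 20 rose, with a median of 1.63.

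Some matrix and fibroblast genes passed as lower again on day 14, a minority of each list. Postn fell by 1.69 (SE 0.308, adjusted p = 0.0191), Lum by 1.39 (SE 0.285, adjusted p = 0.0430), Ccdc80 by 1.18 (adjusted p = 0.0466) and Igf2 by 1.15 (SE 0.218, adjusted p = 0.0246). Fibroblast markers fell in 2 of 15 cases and in 11 adjusted over the list alone (median -0.74, camera adjusted p = 4.36e-09), and extracellular matrix genes in 1 of 23 and in 12 (median -0.74, camera adjusted p = 3.37e-10). Macrophage and monocyte markers had a median of -0.54 (camera adjusted p = 0.00157), the interferon response -0.33 (camera adjusted p = 0.000698) and inflammatory cytokines and NF-kB genes -0.38 (camera adjusted p = 0.0104). Atrial markers (median -0.67, camera adjusted p = 0.0105), angiogenesis factors (-0.29, camera adjusted p = 0.0125) and calcium handling (-0.15, camera adjusted p = 0.0173) were lower too. Higher lists were oxidative phosphorylation (median 0.073, camera adjusted p = 0.000472) and ribosomal proteins (0.064, camera adjusted p = 0.0173), of which Rplp1 rose by 0.77 (SE 0.110, adjusted p = 0.00323). Each of these lists had an adjusted p = 0.819 with an estimated correlation, and endothelial markers (median -0.41, camera adjusted p = 0.0294) had an adjusted p = 0.907 with an estimated correlation. The 2 arrays differed in these lists. Without replicate 1 of iron day 14 angiogenesis factors (-0.053), calcium handling (-0.019), endothelial markers (-0.074), inflammatory cytokines and NF-kB genes (-0.13), oxidative phosphorylation (0.020) and ribosomal proteins (-0.045) were not called. Without replicate 2 the medians were -0.49, -0.23 and -0.79 for angiogenesis factors, calcium handling and endothelial markers, -0.34 for macrophage markers, 0.15 for oxidative phosphorylation and 0.19 for ribosomal proteins. Atrial markers stood at -0.30 without replicate 1 of sham day 1. The total was 83 genes, 59 higher and 24 lower. It was 25 without replicate 1 of iron day 14, 45 without replicate 1 of sham day 1 and 167 without replicate 1 of iron day 1.

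On day 28 transcripts of T lymphocytes joined the clock genes and small nucleolar RNAs. Cd4, the coreceptor of helper T cells, rose by 2.62 (SE 0.38, adjusted p = 0.00264, 2 iron and 3 sham arrays) and Rasgrp1, a signalling protein of T cells, by 2.43 (SE 0.539, adjusted p = 0.0356). Ciart fell by 3.78 (SE 0.255, adjusted p = 1.10e-05), Dbp by 1.66 (SE 0.156, adjusted p = 8.49e-05) and Per2 by 1.38 (SE 0.167, adjusted p = 0.000745). Snora3 rose by 3.23 (SE 0.393, adjusted p = 0.000745) and Snord104 by 3.10 (SE 0.345, adjusted p = 0.000322), with Snord73b (3.20), Snord33 (3.02), Snord82 (2.92) and Snord35b (2.58) close to them. Of the 27 small nucleolar RNAs 23 rose (median 1.64). Lcn2, an iron-binding protein of inflammation, fell by 2.11 (SE 0.395, adjusted p = 0.0148), Postn by 1.81 (SE 0.308, adjusted p = 0.00869) and the collagen gene Col8a1 by 1.79 (SE 0.337, adjusted p = 0.0156). The protease inhibitor gene Timp1 fell by 1.62 (SE 0.348, adjusted p = 0.0324) and Myl1, a myosin light chain, by 1.61 (SE 0.332, adjusted p = 0.0267).

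Among the day 28 lists, clock genes fell in 7 of 18 cases and rose in 2, with 10 and 2 adjusted over the list alone (median -0.53, camera adjusted p = 1.74e-06; adjusted p = 0.356 with an estimated correlation). The lymphocyte list had 2 of 8 members higher and 7 adjusted over the list alone (median 0.73, camera adjusted p = 2.35e-05; adjusted p = 0.426 with an estimated correlation). The cell cycle list had 2 of 15 higher and 8 adjusted over the list alone (median 0.45, camera adjusted p = 0.00318; adjusted p = 0.426 with an estimated correlation). These 2 were the cyclin gene Ccnb2 (0.56, SE 0.121, adjusted p = 0.0330) and the DNA replication gene Mcm2 (0.46, SE 0.102, adjusted p = 0.0357). Beside them, a set of 14 thymocyte genes chosen after the data were seen stood 3.89 and 3.68 above its median over arrays in the 2 day 28 arrays, 2.35 in the sham day 3 array and 1.49 in replicate 1 of iron day 14. The unfolded protein response had 2 of 22 higher and 6 adjusted over the list alone (median 0.22, camera adjusted p = 0.000441; adjusted p = 0.689 with an estimated correlation). Edem1, a factor of protein degradation in the endoplasmic reticulum, rose by 1.36 (SE 0.274, adjusted p = 0.0225). Adipocyte markers had 1 of 4 higher and 3 adjusted over the list alone (median 0.78, camera adjusted p = 0.0244; adjusted p = 0.689 with an estimated correlation). Immediate early genes had a median of 0.32 (camera adjusted p = 0.0177; adjusted p = 0.791 with an estimated correlation), with 0 of 26 passing in limma and 3 at an unadjusted p under 0.05.

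Besides the clock genes, lists of matrix, cell type and metabolic genes were called lower on day 28. Extracellular matrix genes fell in 3 of 23 cases and in 4 adjusted over the list alone (median -0.30, camera adjusted p = 0.000553; adjusted p = 0.690 with an estimated correlation). Fibroblast markers fell in 1 of 15 cases and in 2 (median -0.29, camera adjusted p = 0.0234; adjusted p = 0.791 with an estimated correlation). The fetal and hypertrophy program fell in 3 of 16 cases and in 7 adjusted over the list alone, where 1 rose (median -0.15, camera adjusted p = 0.0137; adjusted p = 0.689 with an estimated correlation). Acta1, skeletal actin, fell by 1.00 (SE 0.228, adjusted p = 0.0413). Atrial markers (median -1.10, camera adjusted p = 0.00316) and glycolysis (-0.077, camera adjusted p = 0.0137) had an adjusted p = 0.689 with an estimated correlation. The atrial median was -0.44 without replicate 1 of sham day 1, whose atrial score of 1.71 was the highest of the arrays. Macrophage and monocyte markers (-0.43, camera adjusted p = 0.000553) and sarcomere genes (-0.072, camera adjusted p = 0.0218) had an adjusted p = 0.690 with an estimated correlation. Antioxidant genes (-0.14, camera adjusted p = 0.00114; adjusted p = 0.426 with an estimated correlation) were lower too. So were the proteasome (-0.10, camera adjusted p = 0.0102; adjusted p = 0.734 with an estimated correlation) and oxidative phosphorylation (-0.055, camera adjusted p = 0.0294; adjusted p = 0.791 with an estimated correlation). Single arrays moved others of these medians, to -0.027 for the proteasome without replicate 1 of iron day 28, -0.027 for sarcomere genes without replicate 2 of sham day 1, and 0.36 for the unfolded protein response and -0.25 for the fetal program without the sham day 3 array. The total was 199 genes, 141 higher and 58 lower. It was 41 and 45 without replicates 1 and 2 of iron day 28, 73 and 86 without replicates 1 and 2 of sham day 1, and 477 without the sham day 3 array.

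**Figure D4:**
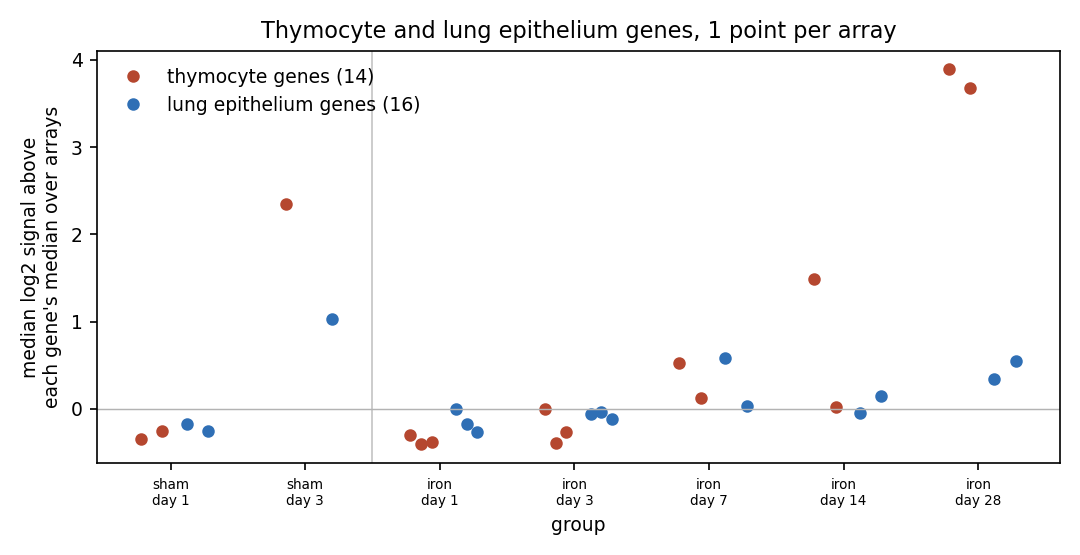
Median log2 signal of 14 thymocyte genes and 16 lung epithelium genes above each gene's median over 15 arrays, with 1 point per array. Thymocyte genes stood at 3.89 and 3.68 in the day 28 arrays and 2.35 in the sham day 3 array, and lung genes were highest in the sham day 3 array at 1.03.

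Averaged over the 5 iron days, some matrix genes and the growth factor gene Igf2 were lower than in sham. Col8a1 fell by 1.33 (SE 0.239, adjusted p = 0.0159, 12 iron and 3 sham arrays), Lum by 1.29 (SE 0.202, adjusted p = 0.00628), Igf2 by 0.98 (SE 0.155, adjusted p = 0.00628), the proteoglycan gene Vcan by 0.98 and Ccdc80 by 0.95. Abca8a, Gpr182 and Ms4a4d fell by 0.87, 0.73 and 0.73. Among higher genes whose arrays did not overlap, the small nucleolar RNA Gm12238 rose most (1.22, SE 0.107, adjusted p = 0.000289). Bcl2l11, which encodes a protein that promotes apoptosis, came next (0.57, SE 0.0987, adjusted p = 0.0112). Ttc8 (0.52), the elongation factor gene Nelfa (0.48), Gdf11 (0.46), Derl2 (0.45), Gm1673 (0.41) and 4933440N22Rik (0.38) also rose. Without the rule on overlap, 20 higher and 7 lower genes that passed differed by more than 2-fold. Of the 27 small nucleolar RNAs 20 passed as higher (median 1), and of the 12 other short structured RNAs 6 did (median 0.697). Clock genes fell in 5 of 18 cases and rose in 2, with 9 and 2 adjusted over the list alone (median -0.33, camera adjusted p = 4.62e-07; adjusted p = 0.359 with an estimated correlation). Fibroblast markers fell in 3 of 15 cases and in 12 adjusted over the list alone (median -0.70, camera adjusted p = 1.50e-12), and extracellular matrix genes in 3 of 23 and in 15 (median -0.57, camera adjusted p = 1.16e-12), both with an adjusted p = 0.591 with an estimated correlation. Macrophage and monocyte markers (median -0.49, 8 of 17 lower adjusted over the list alone, camera adjusted p = 2.69e-07), atrial markers (-0.63, camera adjusted p = 0.00177) and smooth muscle and pericyte markers (-0.35, camera adjusted p = 0.00687) had an adjusted p = 0.676 with an estimated correlation. Endothelial markers (-0.41), angiogenesis factors (-0.26), calcium handling (-0.064) and the interferon response (-0.14) were called lower, and immediate early genes (0.27) and heat shock proteins (0.19) higher, with camera adjusted p from 0.000202 to 0.0384 and an adjusted p = 0.723 with an estimated correlation. Without replicate 1 of sham day 1 the medians were -0.25 for atrial markers, -0.16 for angiogenesis factors and -0.20 for smooth muscle and pericyte markers. That of calcium handling was -0.037 without replicate 1 of iron day 14, and that of the interferon response -0.088 without the sham day 3 array. The total was 113 genes, 67 higher and 46 lower. It was 296 without replicate 1 of iron day 1, 174 without replicate 1 of iron day 7, 64 and 60 without replicates 1 and 2 of iron day 28, and 30 and 56 without replicates 1 and 2 of sham day 1.

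The comparison of late iron arrays (days 7, 14 and 28) with early ones (days 1 and 3) takes no difference from the sham arrays, which enter only its error variance, and gave the most genes. Ciart fell by 3.31 (SE 0.161, adjusted p = 1.71e-07, 6 arrays on each side), Dbp by 1.82 (SE 0.0984, adjusted p = 3.38e-07), Per3 by 1.68 and Per2 by 1.58, while Arntl rose by 2.43 (SE 0.183, adjusted p = 4.95e-06). Clock genes fell in 13 of 18 cases and rose in 3, with 14 and 3 adjusted over the list alone (median -0.77, camera adjusted p = 2.66e-07; adjusted p = 0.205 with an estimated correlation). Other falls were in Tfrc, the transferrin receptor (-1.08), the phospholipase gene Pla2g4e (-1.07), Tef (-1.04) and the cell cycle kinase gene Wee1 (-0.93). Cd8b1, a coreceptor chain of cytotoxic T cells, rose by 3.11 (SE 0.648, adjusted p = 0.00581) and H2-Aa by 2.10 (SE 0.158, adjusted p = 4.95e-06), with Rasgrp1 (2.11) and the lymphoid adaptor gene Sla (2.06). Snora3 (2.29), Snora74a (2.27) and Snord82 (2.13) rose, and 24 of 27 small nucleolar RNAs did so (median 1.35).

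Immune and stromal markers were higher in the late arrays, where mean lymphocyte scores were 0.89, -0.01 and 1.22 on days 7, 14 and 28 against -0.84 and -0.72 on days 1 and 3. All 8 genes of the lymphocyte list rose, also adjusted over the list alone (median 1.81, camera adjusted p = 2.43e-10; adjusted p = 0.205 with an estimated correlation). Thymocyte signal lay unevenly across the same arrays, at 3.89 and 3.68 on day 28, 1.49 in replicate 1 of iron day 14 and 0 or lower in the 6 early iron arrays. Of 17 macrophage and monocyte markers 15 rose late minus early, and 16 rose adjusted over the list alone (median 0.94, camera adjusted p = 1.25e-12; adjusted p = 0.373 with an estimated correlation). Fibroblast markers rose in 12 of 15 cases, over the list alone too (median 0.63, camera adjusted p = 8.19e-08). Endothelial markers rose in 4 of 18 and in 8 adjusted over the list alone (median 0.46, camera adjusted p = 0.000127) and extracellular matrix genes in 7 of 23 and in 10 (median 0.36, camera adjusted p = 0.000127). The interferon response had 9 of 16 higher (median 0.33, camera adjusted p = 3.28e-06) and inflammatory cytokines and NF-kB genes 5 of 16 (median 0.30, camera adjusted p = 0.00101). The unfolded protein response had 10 of 22 with 1 lower (median 0.24, camera adjusted p = 0.000815). Adjusted over the list alone the counts of these 3 were the same. These 6 lists had an adjusted p = 0.461 with an estimated correlation. Ribosomal proteins rose in 17 of 30 cases and in 22 adjusted over the list alone, by a median of 0.19 (camera adjusted p = 2.43e-10; adjusted p = 0.373 with an estimated correlation), among them Rpl34 (0.35, SE 0.0371, adjusted p = 0.000116). The cell cycle list had 6 of 15 higher, over the list alone too (median 0.15, camera adjusted p = 0.00196; adjusted p = 0.373 with an estimated correlation). With single arrays left out its median ran from 0.050 to 0.23, and that of inflammatory cytokines and NF-kB genes was 0.15 without replicate 1 of iron day 7.

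Cardiomyocyte lists were lower in the same comparison by small amounts. Sarcomere genes fell in 11 of 21 cases and in 13 adjusted over the list alone (median -0.12, camera adjusted p = 0.000431), with Tcap, a protein that caps titin, lower by 0.90 (SE 0.118, adjusted p = 0.000421). The tricarboxylic acid cycle fell in 8 of 19 and in 12 adjusted over the list alone (median -0.14, camera adjusted p = 0.000129), and ion channels in 8 of 20 on both counts (median -0.21, camera adjusted p = 0.000510). Glycolysis had 7 of 21 lower and 9 adjusted over the list alone, with 1 higher on both counts (median -0.14, camera adjusted p = 0.00191), and calcium handling 6 of 19 and 8, with 1 and 2 higher (median -0.077, camera adjusted p = 0.0434). These 5 lists had an adjusted p = 0.461 with an estimated correlation. Fatty acid oxidation had 6 of 29 lower and 2 higher (median -0.11, camera adjusted p = 0.0160; adjusted p = 0.611 with an estimated correlation). The fetal and hypertrophy program had 4 of 16 lower and 1 higher (median -0.22, camera adjusted p = 0.0429; adjusted p = 0.470 with an estimated correlation), and the proteasome 2 of 27 lower (median -0.11, camera adjusted p = 0.0175; adjusted p = 0.593 with an estimated correlation). Adjusted over the list alone these were 9 and 2, 7 and 1, and 0 for the proteasome. The total was 2194 genes, 1027 higher and 1167 lower, and 163 of the higher but 9 of the lower differed by more than 2-fold. It was 1275 without replicate 1 of iron day 7, and 1247 and 1433 without replicates 1 and 2 of iron day 28. With the fibroblast and macrophage marker means as covariates it was 6, with an SE 1.89 times as large for the median gene. Snora3 then stood at 1.92 (SE 0.513, 0.249 without covariates), Tfrc at -0.96 (SE 0.398, 0.2 without) and Cd8b1 at 1.44 (SE 1.22, 0.648 without). Calls were thus lost to precision as well as to smaller differences.

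**Figure D5:**
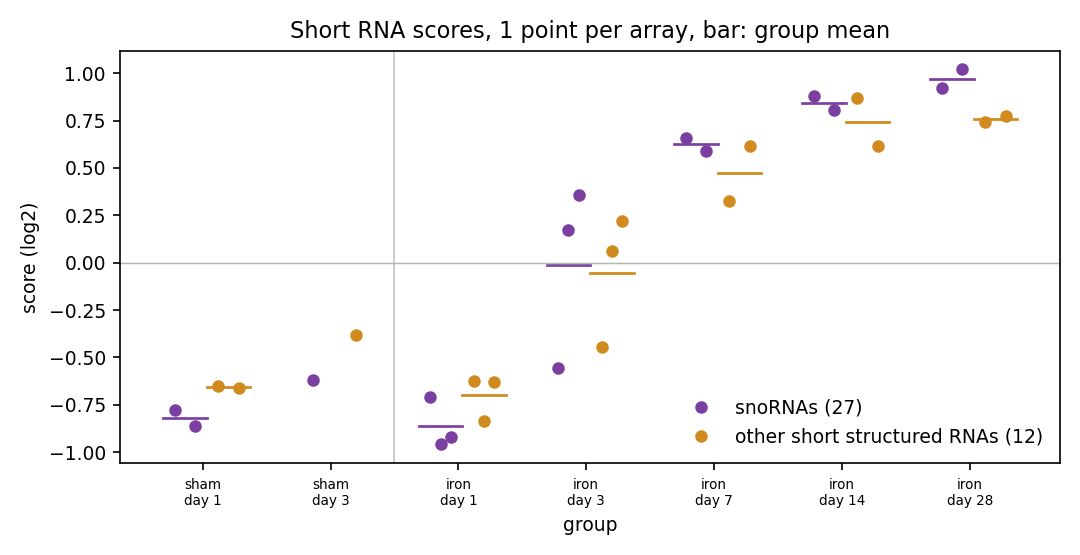
Mean log2 signal of 27 small nucleolar RNAs and 12 other short structured RNAs, each gene centred on its mean over 15 arrays, with 1 point per array and a bar at each group mean. Of the 27 small nucleolar RNAs 24 rose in late minus early iron (median 1.35), and of the 12 others 11 rose (median 0.91).

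Among the 5 iron days, 1911 genes differed in limma's F test. The 12 with the smallest p were the clock and clock-controlled genes Ciart, Dbp, Per3, Per2, Arntl and Usp2, the small nucleolar RNAs Snord49b, Snora21, Snord15b and Snora16a, and the class II genes H2-Aa and H2-Eb1, with adjusted p from 4.14e-06 to 0.000151. The total was 1271, 1057 and 1234 without replicates 1, 2 and 3 of iron day 3, 1093 without replicate 1 of iron day 7, and 611 and 693 without replicates 1 and 2 of iron day 28. In no comparison were the lists of DNA repair, apoptosis regulators, cardiac transcription regulators or Schwann and neuronal markers called. On day 3 their medians were 0.041, -0.16, 0.076 and -0.016, with camera adjusted p of 0.818, 0.150, 0.525 and 0.818. Bcl2l11 (0.73, SE 0.124, adjusted p = 0.00745) rose within the apoptosis list on that day, and Casp12 (-0.60, SE 0.0999, adjusted p = 0.00679) and Casp8 (-1.13, SE 0.267, adjusted p = 0.0245) fell. Median, mean and test shared their sign for every called list. They did not for some lists without a call, such as apoptosis regulators and p53 targets on day 28. Neutrophil and erythroid markers had 1 and 2 tested members and were not tested as lists.

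The single sham array of day 3 differed from the 2 sham arrays of day 1 in 38 genes, 32 higher and 6 lower, with the lone array assumed to vary like the other groups. Sec14l3 (3.39, adjusted p = 0.000250), Cfap126 (2.30, adjusted p = 0.000104), a gene of motile cilia, and Krt8 (2.05, adjusted p = 0.0167), an epithelial keratin gene, were among the higher ones, and so was Cd8b1 (4.29, adjusted p = 0.0275). These 4 were picked after the values were seen. The count was 78 without either array of iron day 7, 25 without either array of iron day 28, and 7 and 6 without replicates 1 and 2 of sham day 1.

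The day comparisons share their sham arrays, which alone can make them alike. Days 1 and 3 correlated at r = 0.795 across genes, where simulated unchanged groups against the same sham arrays gave 0.497, with a covariance of 0.0659 against a simulated 0.0103. All 6 genes lower on day 1 were also lower on day 3, against 0.315 for independent lists. Days 3 and 14 correlated at 0.663 (simulated 0.454), days 7 and 14 at 0.509 (0.406), days 7 and 28 at 0.491 (0.401), days 1 and 14 at 0.522 (0.448) and days 14 and 28 at 0.411 (0.402). Days 1 and 7 (-0.114, simulated 0.448) and days 1 and 28 (-0.0732, 0.445) were less alike than the simulated unchanged groups. Days 3 and 7 (0.183, 0.447) and days 3 and 28 (0.172, 0.450) had a lower r but a higher covariance than these (0.0191 against 0.0104, and 0.0182 against 0.0105). Days 7 and 14 shared 45 higher and 16 lower genes (1.14 and 0.64 for independent lists), days 7 and 28 shared 59 and 18 (2.73 and 1.55), and days 14 and 28 shared 43 and 11 (0.834 and 0.14). Days 3 and 7 shared 52 higher and 13 lower genes (5.38 and 14 for independent lists), and 6 genes passed in opposite directions. Unchanged groups shared 0 calls in limma over 50 simulations. Few calls are made at this threshold where nothing differs, so this 0 does not gauge the shared calls. The counts for independent lists take no account of the shared sham arrays. With 3 sham arrays the controls were not split, so part of the excess may come from the shared arrays.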

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

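The tests of the hour of collection, of the cell mix behind the clock genes, of an equal loss of all other cells with its pairs of lists, of thymic tissue and of short RNA handling, and the look at the make-up of the splits, were chosen only after the results were seen. Signals differed between the iron days, by tests of the difference itself, and no sham array later than day 3 parts an iron effect from time. The F test gave 1911 genes and late minus early iron gave 2194. Of 100 splits of the iron arrays the highest other gave 225 genes for the F test, and 1505 for late minus early (1 of 100 splits each as large). A random labelling of these arrays thus seldom gave as many genes. The splits treat arrays as separate units, which the labels do not state, so chance differences between a few preparations were not excluded. The split that gave 1505 parted early from late arrays except for 1 array exchanged on each side. For all iron days minus sham the real split gave 113 and the highest other 1 (1 of 100 as large). Those splits also mixed the iron days, whose differences then widen the error, so they cannot exclude chance for iron against sham. For days 1 and 3 the 10 splits are too few for a share under 0.05 (real 6 and 801, highest other 0 in limma, 1 split each as large).

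Genes with a late minus early difference were Ciart (-3.31), Dbp (-1.82), Per3 (-1.68), Per2 (-1.58), Tfrc (-1.08), Pla2g4e (-1.07), Tef (-1.04) and Wee1 (-0.934) on the lower side. On the higher side they were Cd8b1 (3.11), Arntl (2.43), Snora3 (2.29), Snora74a (2.27), Snord82 (2.13), Rasgrp1 (2.11), H2-Aa (2.10) and Sla (2.06). List medians that differed between late and early arrays were 1.81 for lymphocyte, 0.937 for macrophage, 0.634 for fibroblast and 0.462 for endothelial markers, 0.364 for extracellular matrix, 0.331 for the interferon response and 0.303 for inflammatory cytokines and NF-kB genes. Those of the unfolded protein response (0.242), ribosomal proteins (0.189) and the cell cycle (0.147) were also higher. Lower medians were -0.772 for the circadian clock, -0.217 for the fetal and hypertrophy program, -0.209 for ion channels, -0.136 for the tricarboxylic acid cycle, -0.135 for glycolysis, -0.122 for sarcomere genes, -0.113 for fatty acid oxidation, -0.113 for the proteasome and -0.0772 for calcium handling.

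Clock genes were opposed in the late iron arrays. A differing share of macrophages as the cause is argued against. The median of the evening genes was -0.906 (SE over genes 0.22) on day 7 and -0.807 (SE over genes 0.25) on day 14. That of macrophage markers went from 0.557 to -0.542. An SE over genes treats genes of the same arrays as separate and does not measure the spread between arrays. Other cell types were not in this test. The mean fibroblast score was lower than in sham (0.615) on both days (0.354 and -0.208), so a part of fibroblasts was not tested. A different hour of tissue collection could shift the morning genes (0.445) away from the evening genes (-0.92), a gap of 1.37 (SE over genes 0.75) for 14 genes. It stays open, because no hour is in the labels and no sham array is later than day 3. An effect of iron ions or of time on the clock is equally untested.

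Transcripts of cells other than cardiomyocytes differed between groups. Residuals of the 15 fibroblast markers correlated at 0.77 on average (95th percentile of 2000 random lists 0.102). A fibroblast share that varies from preparation to preparation may thus account for part of these differences. The correlation does not tell how large a part. The fibroblast score varied most within iron day 1 (SD 0.592), and little within sham (mean 0.615, SD 0.0735) and iron day 3 (mean -0.704, SD 0.0901). An equal loss of all other cells on day 3 stays open, with the fibroblast median 0.197 below the endothelial one (-0.197, two-sided permutation test, p = 0.26). By the same test 7 of 21 pairs of cell type lists lay apart (adjusted p under 0.05, gaps of 0.394 to 1.36), but among the genes of the stricter filter, away from the floor, 0 of 10 did (0 also at an unadjusted p under 0.05), and the 4 pairs with adipocyte or Schwann lists had too few genes to be tested there. Thymic tissue in the day 28 preparations may explain the T cell, cell cycle and histone genes there, since 100% of the 12 that passed (30.6% of all genes) also stood above both sham day 1 arrays in the sham day 3 array, which had no iron. An effect of iron ions on the resident cells remains untested.

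Small nucleolar RNAs were higher in the late iron arrays. For those that were matched to a protein-coding host, an equal rise of the host's RNA is argued against. The 11 hosts had a median of 0.11 (SE over genes 0.042) and their small nucleolar RNAs 0.893 (SE over genes 0.23). These SEs do not measure the spread between arrays. Not all of the 27 small nucleolar RNAs were matched to a host, and Snord104, Snord33 and Snord35b were among those left out. Rpl27a (0.32), Rps3 (0.282) and Hspa8 (0.164) passed as higher in limma, and the other hosts did not pass. The arrays measure RNA level, so transcription of the hosts was not itself tested. Handling or recovery of short RNA could raise the small nucleolar RNAs, since 11 of 12 other short structured RNAs rose too. The median of the 12 was 0.91 (SE over genes 0.18), beside 1.35 (SE over genes 0.13) for the small nucleolar RNAs. Snord73b (2.444), which is among these 12 by its annotation, is a small nucleolar RNA by its name. On iron day 3 replicate 1 had a score of -0.556 for the small nucleolar RNAs and -0.444 for the other short RNAs. Replicates 2 and 3 stood at 0.171 and 0.355, and at 0.064 and 0.218. Both classes thus differed between arrays of the same day. The handling explanation stays open, because the labels name no handling batch and no sham array is later than day 3. An effect of iron ions or of time was not tested apart from it.

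Probe sets without a single gene name, which the comparisons did not use, also held differences. Of 3478 above the filter, 156 passed on day 3 (70 higher, 86 lower), 166 on day 7 (105 and 61), 83 on day 14 (75 and 8) and 121 on day 28 (91 and 30), against 0 on day 1 (limma, 276 at an unadjusted p under 0.05).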

How the results depend on the processing

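Marker scores as covariates and the fit with 3 outlying arrays left out (sham day 3, replicate 1 of iron day 7 and replicate 1 of iron day 14) were chosen after seeing the data, and the other choices were made before the data were examined. Of 118 named gene results, 30 kept their direction and side of the threshold at every alternative run. These were all 12 of the F test, 5 of 16 in late minus early iron (Ciart, Dbp, Per2, Per3 and Arntl), 4 of 16 on day 14 (Ciart, Dbp, Per2 and Per3), 6 of 16 on day 28 (Ciart, Dbp, Per2, Snora3, Snord104 and Snord35b), Gm12238 over all iron days, and Cntn5 and Mtm1 on day 1, which never passed. Late minus early, Ciart ranged from -3.45 to -3.18 and Arntl from 1.58 to 2.58. None of the 16 results on day 3 or day 7 kept its call throughout. On day 7 Ciart, Dbp, Per2, Per3, Tef and Snord104 lost it only with the marker scores. With them Ciart was -3.00 (SE 0.563), Dbp -1.87 (SE 0.324) and Tef -0.77 (SE 0.286). Among the day 3 results that lost the call only with the marker scores were Apod (-0.44, SE 0.348), Aspn (-0.67, SE 0.413) and Lum (-0.36, SE 0.204). Fibroblast markers such as Lum are part of the score they were adjusted for, so their move towards 0 was built in. Where a result moved, the cause was not tested unless stated.

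The day 1 count of 6 genes was 0 with quantile normalization (limma, 1132 at an unadjusted p under 0.05), 0 with no filter (2067), 0 with all probe sets (1436), 0 with only the arrays compared (883) and 0 with the sham day 1 arrays as the control (635). It was 2 with no intensity trend and 69 with array weights. Array weights gave 1691 genes on day 3, 243 on day 7, 2448 on day 28, 356 over all iron days, 4051 in the F test and 117 for the sham days. The stricter filter, which tests fewer genes, gave 451 on day 3, 107 on day 28, 49 over all iron days and 22 for the sham days, and no filter gave 238 for the sham days. All probe sets gave 763 on day 7, 178 on day 14, 334 on day 28 and 221 over all iron days. Only the arrays compared gave 45 on day 7. The sham day 1 arrays as the control gave 270 on day 3 and 476 on day 28, and the sham day 3 array as the control gave 477 on day 3. Median centring moved the share of higher genes from 34.7% to 46.1% on day 3 and from 42.0% to 54.4% on day 7.

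With the replicate block, which leaves out the sham day 3 array, day 1 gave 0 genes (limma, 551 at an unadjusted p under 0.05), day 3 157, day 14 54, day 28 395, all iron days 48, late minus early 1444 and the F test 1249. Whether the replicate numbers pair the samples was not settled, so this fit is a check only.

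With marker scores as covariates day 1 gave 0 genes (limma, 302 at an unadjusted p under 0.05), day 3 0 (576), day 7 1, day 14 24, day 28 573, all iron days 5, late minus early 6 and the F test 153. The SE of the median gene grew 1.90 times on day 3 and 1.89 times late minus early, so part of the loss of calls came from precision. Cd24a on day 3 reversed there, to 0.963 (SE 1.19). With the 3 outlying arrays left out, day 1 gave 2 genes, day 3 517, day 7 105, day 14 21, day 28 774 and late minus early 1284, and the median of ribosomal proteins on day 14 reversed to -0.0955.

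Leaving out single arrays gave 0 to 363 genes on day 1, 126 to 1080 on day 3, 46 to 555 on day 7, 25 to 167 on day 14, 41 to 477 on day 28, 30 to 296 over all iron days, 1247 to 2709 for late minus early, 611 to 2576 in the F test and 6 to 78 for the sham days. The arrays behind the widest moves are named in the report beside each count. Without replicate 1 of sham day 1 the atrial median on day 1 reversed to 0.028 (range -0.67 to 0.028), and without replicate 1 of iron day 14 the ribosomal protein median on day 14 reversed to -0.0453 (range -0.0453 to 0.192).

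Of the 105 list calls, 0 were kept with an estimated correlation (camera in limma, at an unadjusted p under 0.05: 5 on day 1, 3 on day 3, 2 on day 7, 1 on day 14, 3 on day 28, 2 over all iron days and 4 late minus early). The fry test called 0 lists on day 1 (limma, 7 at an unadjusted p under 0.05), 5 on day 3, 2 on day 7, 1 on day 14, 3 on day 28, 1 over all iron days and 14 of 19 late minus early. No filter gave 23 lists on day 7, where 14 were called with the filter. Leaving out single arrays gave 10 to 17 lists on day 1 (10 without replicate 2 of iron day 1), 13 to 19 on days 3, 7 and 28, 8 to 14 on day 14, 9 to 14 over all iron days and 17 to 20 late minus early. Pseudocounts of 1 and of 64 were not run, since the values were already log2.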

Other observations

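Histone genes were grouped after the values were seen. Of 20 tested, 8 rose on day 28 (median 1.10) and 14 rose late minus early (median 0.76). On day 1 their median was -0.45, with 0 passing in limma.

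The sham day 3 array held the highest signal of 11 of 16 lung epithelium genes, where 1.1 would be so if arrays were alike. These genes were listed after the values were seen, so the 1.1 is not a chance level for them. The club cell gene Scgb1a1 stood at 12.37 there and at most at 11.88 elsewhere, Cyp2f2 at 11.6 and 9.76, and the surfactant gene Sftpc at 7.38 and 5.31. The median of lung genes was 1.03 in that array, 0.58 in replicate 1 of iron day 7, and 0.34 and 0.55 in the arrays of iron day 28. The thymocyte genes stood at 2.35 in the sham day 3 array and at 0.53 in replicate 1 of iron day 7. The erythroid genes Alas2 and Slc4a1 stood at -1.58 (SE 1.03) and -1.19 (SE 0.804) on day 1 and at -2.46 (adjusted p = 0.144) and -2.33 (adjusted p = 0.0878) on day 3, and passed on neither day in limma. Their score ranged from -2.18 to 1.64 between the arrays of iron day 1.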
